A study of Danio rerio with 5 samples.

How the data were processed

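The series holds 5 droplet libraries from zebrafish caudal fin, made with the 10x Genomics Chromium 3' version 2 kit, 1 each from uninjured fin and from fin at 1, 2, 3 and 4 days post amputation (dpa). Per the labels' protocols, the distal 2 mm of the regenerate was taken, cells were freed with Liberase, and cells that excluded SYTOX Blue were sorted for red and against green fluorescence, so that krt1-19e:h2az2a-mCherry marked basal and krt4:LY-EGFP superficial epidermal cells. The labels disagree on the uninjured sample, which is placed at the distal edge of the fin in the treatment protocol and at mid-fin in the extraction protocol, so where it was cut is not known. They name nuclear RNA as the molecule although the protocol describes whole dissociated cells. The number of fish behind each library is not stated. The library at 4 dpa is named "injured" in its deposited matrix and was used as 4 dpa from its label.

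The deposited values are UMI counts per gene and barcode, as whole numbers with no scaling, in matrices whose barcodes are a called subset per the file headers' names. Cell Ranger 7.0.0, Seurat 5.3.0 and the build danRer11 are named, per the submitters' processing notes, with no role or order, and no filter on barcodes is stated. The matrices list 27407 features with Ensembl identifiers, including EGFP and not mCherry. Of these, 20046 carry a symbol in the files, 5027 others were named from the Ensembl name table, and 2334 kept their identifier only. 630 features share a symbol with another, and a near-identical copy can take part of such a gene's counts in ways that cannot be resolved here. Of the 343 gene names in the fixed lists and marker sets, 334 matched a feature.

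Cells were kept with at least 500 UMIs, at least 300 genes and under 10% mitochondrially encoded UMIs, and the cells with the highest doublet scores (scrublet in scanpy 1.11.5) were removed up to 0.8% per 1000 barcodes, which took out 57, 338, 204, 242 and 75 cells of the uninjured, 1, 2, 3 and 4 dpa libraries. This kept 37.0%, 53.8%, 38.3%, 43.6% and 46.1% of barcodes, and 26.4%, 14.1%, 31.4%, 23.4% and 18.0% of barcodes had over 50% mitochondrially encoded UMIs. Counts were normalised to 10000 per cell and logged, 2000 variable genes were centred within each library, and 30 principal components and 15 nearest neighbours gave clusters by the Leiden method (leidenalg 0.10.2, resolution 0.5, seed 1). Clusters were named from 14 marker sets fixed beforehand, as "-like", and a cluster without a clear set stayed unnamed. mCherry is not among the features, so the red gate could not be checked, and centring within libraries can still leave clusters made of 1 library.

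The gene lists, marker sets, cell filters, comparisons, tests, rules for naming genes and alternative settings were fixed before the data were examined, except for the alternatives, cell sets and tests of explanations that the closing section names as chosen later. The 22 lists cover SP factors of the limb and fin epidermis, other SP genes, Fgf ligands, Fgf response, Wnt ligands, Wnt response, Hedgehog, BMP, fin fold and limb ridge factors, wound epidermis, basement membrane and hemidesmosome, desmosome and cell adhesion, keratins, S phase, G2/M, immediate early and heat shock, inflammatory, interferon and antigen presentation, glycolysis, mitochondrially encoded, retinoic acid and actin cytoskeleton genes. Some lists share functions with the marker sets, such as krt4 and krt1-19e, fras1 and col17a1a.

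Comparisons between groups have 1 library on each side, so they carry no test, standard error or count of changed genes. UMI counts were summed over the epidermal cell set, which is all kept cells outside clusters named as a non-epidermal type and includes unnamed clusters, and turned into counts per 1000000 (CPM). Each level has an exact Poisson 95% interval and each log2 ratio an exact conditional binomial 95% interval, and both cover counting error only. Where 1 side had 0 UMIs the fold is a lower bound from 3 counts. The list medians need at least 3 members with at least 5 CPM in 1 of the libraries compared, take members with 0 UMIs at 3 counts, and were placed among 10000 random lists of the same size matched on mean expression. Only 4 dpa against uninjured and the ratios among 1, 2 and 3 dpa are within a labelled batch.

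The genes named are, for comparisons of libraries, the 10 highest and 10 lowest ratios among genes with at least 50 CPM in the higher library, leaving out ribosomal protein genes, mitochondrially encoded genes and clone names; for the 4 ratios to uninjured, the same by the ratio nearest to 1. From each list up to 4 members with the largest ratios could be named. sp6, sp8a, sp8b, sp9, krt1-19e, krt4 and h2az2a were always reported. For the tested contrasts they are the 10 highest and 10 lowest fold changes among called genes that went 1 way in every library, with at least 20 CPM in the higher arm. The CPM of each named gene in the other cell classes was also computed.

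Shares of cells with an sp UMI were taken after thinning each cell to 1000 UMIs at random and leaving out shallower cells (131, 168, 144, 340 and 49 of the epidermal cell set), with exact Clopper-Pearson 95% intervals. For the sp8 and sp6 contrasts, UMI counts were summed per library over cells with a UMI of sp8a or sp8b, or of sp6, and over as many cells with none from the same library and UMI decile, in every library with at least 20 detected cells. They used 152, 160, 329, 321 and 147 cells per arm for sp8 and 22, 107, 340, 307 and 71 for sp6. edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, library as a block) in R 4.3.3 gave log2 fold changes and Benjamini-Hochberg adjusted p values, with a threshold of 0.05, and the defining genes were left out. DESeq2 1.42.0 was an alternative test. The p values measure how regularly the arms differ across these 5 libraries, each from another time point. The standard errors were derived from the fold change and its F statistic.

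On data simulated for the sp8 contrast with 8897 genes, 60% of genes changed by 1 log2 unit and 100.0% of those changed by 2 were recovered with 2 unchanged genes called. For the sp6 contrast with 6556 genes these were 59% and 100.0%, with 10 unchanged genes called. The genes changed in both had mean counts of at least 10. For 4 dpa against uninjured in basal-epidermal-like cells, 8070 genes with at least 10 expected UMIs were assessed on simulated Poisson counts. Median estimates were 0.99 and −1.01 for true changes of 1 and −1, and 96.2% of the intervals held the truth. Such counts meet the intervals' own assumption, so this does not show how the intervals perform across animals.

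The alternatives were other cell filters, no doublet removal, all kept cells or basal-epidermal-like cells in place of the epidermal cell set, TMM and DESeq2 scaling of the library sums, equal weight per cell, thinning, other limits on low values, other clustering settings, and for the contrasts another test, scaling, filter, draw, matching or block and each library left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used. No deposited column was left unmapped to a sample.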

Results

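Single-cell RNA counts were collected from the caudal fin of zebrafish carrying krt1-19e:h2az2a-mCherry, which marks basal epidermal cells, and krt4:LY-EGFP, which marks superficial epidermal cells. Per the labels, live cells with red and without green fluorescence were sorted from uninjured fin and from regenerating fin at 1, 2, 3 and 4 days post amputation (dpa), with 1 library per group and 5 libraries in all. The labels put the uninjured and 4 dpa libraries in batch 1 and the 1, 2 and 3 dpa libraries in batch 2. The deposited matrices held 4302 barcodes and 16115572 UMIs in the uninjured library, 8559 and 23294805 at 1 dpa, 7903 and 18736220 at 2 dpa, 8056 and 13717980 at 3 dpa, and 4417 and 24528686 at 4 dpa. After filtering, 1593, 4602, 3028, 3509 and 2038 cells were kept, in the same order, with median depths of 5654, 3713, 3765.5, 2595 and 9404.5 UMIs per cell. No group had a replicate, so every interval between groups covers counting error only and no difference between groups has a replicate check.

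Although the labels describe a sort for basal epidermal cells, cells with leukocyte markers, pooled over their types, outnumbered basal-epidermal-like cells in all 5 libraries. mCherry is not a feature of the matrices, so whether these hold the red and not green cells could not be checked. Basal-epidermal-like cells, named from markers such as krt1-19e, tp63 and col17a1a, were 17.5% of kept cells in the uninjured library (exact 95% interval 15.7 to 19.5), 11.5% at 1 dpa, 25.2% at 2 dpa, 28.9% at 3 dpa and 11.3% at 4 dpa (9.94 to 12.7). Leukocyte-like cells, mainly of clusters named macrophage- or dendritic-like from markers such as mpeg1.1, cd74a and marco, were 25.6% (23.5 to 27.8), 38.2%, 38.7%, 41.2% and 63.9% (61.8 to 66.0). In clusters 2 and 14, which held 1041 of the 1182 cells so named at 4 dpa and 259 of the 355 in the uninjured library, 10 and 8 of these markers were raised. The 10 leading genes of each held the lymphocyte marker cd8a and none of them. No other cluster named macrophage- or dendritic-like had any of these markers among its 10 leading genes either. The leading genes were ranked against all other kept cells, other clusters of the same name included. Markers that several of these clusters share can therefore be missing there. The marker mfap4 matched no feature, and mfap4.2 was among the leading genes of cluster 2. The leukocyte-like cells include cluster 20, whose 10 leading genes held spp1 of the osteoblast marker set and no gene of the leukocyte marker sets. Its cells also had 3 macrophage or dendritic markers raised, so leaving it out does not show that they were not leukocytes. Without cluster 20 the leukocyte-like cells were 25.6%, 36.1%, 37.0%, 40.5% and 63.5%. Mesenchymal-like and osteoblast-like cells together were 12.99%, 39.9%, 17.7%, 9.72% and 9.86%. Superficial-epidermal-like cells, all of cluster 7, were 12.7%, 3.76%, 5.91%, 6.16% and 7.02%, and intermediate-epidermal-like cells were 3.64%, 5.45%, 9.58%, 10.0% and 0.785%. In cluster 7 the level of 8 superficial markers was raised, but its 10 leading genes held the basal marker krt1-19d and no superficial marker. Cells of clusters whose markers named no type were 27.6% of the uninjured library, against 1.195%, 2.91%, 3.96% and 7.12% at 1 to 4 dpa.

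**Figure D1:**
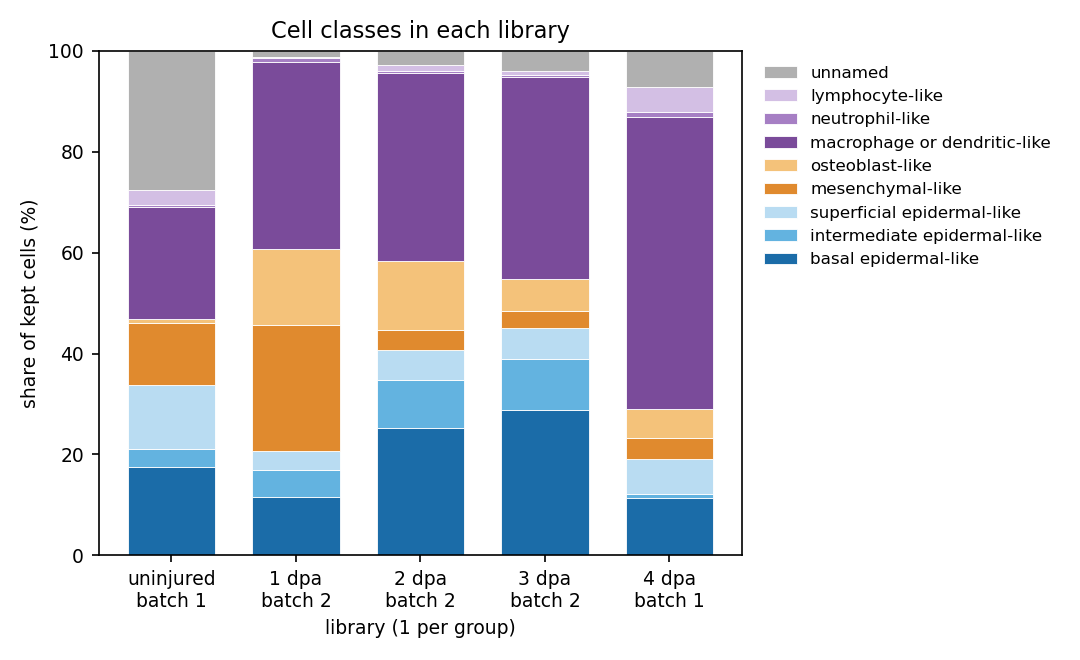
Each stacked bar gives the percent of kept cells in each marker-named class for 1 library, from uninjured to 4 dpa. Leukocyte-like cells took 25.6% of the uninjured bar and 63.9% of the 4 dpa bar, and unnamed cells took 27.6% of the uninjured bar.

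The comparisons of gene expression use the epidermal cell set, meaning all kept cells outside clusters named as a non-epidermal type, which held 978, 1009, 1319, 1721 and 534 cells. Unnamed cells were 44.9% of that set in the uninjured library and 27.2% at 4 dpa, against 5.45%, 6.67% and 8.08% at 1, 2 and 3 dpa, so values in basal-epidermal-like cells alone stand beside it. Those basal-epidermal-like cells also fell into different clusters by library. In the uninjured library 97.85% were of a cluster led by zgc:136930, itgb4, which encodes a hemidesmosome integrin, and krt1-19e. At 1 dpa 97.55% were of a cluster with EDNRB and hbegfb among its leading genes. At 2, 3 and 4 dpa they were divided between a cluster led by lgals1l1, col17a1a and krt1-19e (50%, 52.4% and 57.8%) and a cluster led by ecm2, enam, frem2b, frem2a, fras1, col7a1 and sp6 (46.7%, 47.5% and 41.7%).

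The comparison of 4 dpa with uninjured fin asked how epidermal cells of the regenerate differed from those of intact fin within 1 labelled batch. All 4 SP transcription factor genes of the limb and fin epidermis were higher at 4 dpa. sp6 (ENSDARG00000099880) stood at 62.3 UMIs per 1000000 (CPM) against 3.41, a log2 ratio of 4.19 (95% interval 3.60 to 4.85). sp9 (ENSDARG00000099374) had a log2 ratio of 1.23 (0.81 to 1.66), sp8a (ENSDARG00000011870) 1.02 (0.80 to 1.25) and sp8b (ENSDARG00000056666) 0.98 (0.21 to 1.76). In basal-epidermal-like cells alone sp6 stood at 143 CPM against 2.72, a log2 ratio of 5.72 (4.72 to 6.94), and sp8a, sp8b and sp9 had log2 ratios of 1.11, 1.05 and 1.42. After thinning to 1000 UMIs a cell sp8b was lower in them (−0.24), and over all kept cells sp8a was lower (−0.44). The thinned sp8b value rests on few UMIs and does not settle the direction. Another random thinning to that depth found sp8b in 2 of 208 basal-epidermal-like cells at 4 dpa against 1 of 265 uninjured. Of the genes behind the sort, krt1-19e had a log2 ratio of −0.06, h2az2a 0.46 and krt4 1.18 in the epidermal cell set, and krt4 was at −0.81 over all kept cells. The counts of h2az2a cannot separate the endogenous gene from the transgene.

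The genes with the highest ratios at 4 dpa included enamelin (enam), an enamel matrix protein, at 2836 CPM against 1.5, a log2 ratio of 10.89 (10.05 to 11.89). The type X collagen gene col10a1a stood at 777 CPM against 0 UMIs, at least 1900-fold higher, and and1, which encodes actinodin of the fin fold's actinotrichia, at 251 CPM against 0 UMIs, at least 614-fold higher. The secretory calcium-binding phosphoprotein genes scpp7 and scpp5 were at least 359-fold and 224-fold higher, and the proteoglycan genes ogna and dcn had log2 ratios of 6.72 and 4.69. The metalloprotease gene adam8a had a log2 ratio of 8.03, clu, which encodes the secreted chaperone clusterin, 9.37 (6.89 to 14.68), and ecm2 4.70. Several of these genes were also abundant in other cells of the 4 dpa library, with col10a1a at 7977 CPM and clu at 5119 CPM in osteoblast-like cells and adam8a at 1402 CPM in neutrophil-like cells. In basal-epidermal-like cells alone, enam stood at 6920 CPM against 3.75 (log2 ratio 10.85), col10a1a at 1898 CPM against 0 UMIs (at least 1858-fold higher) and frem2a, of the Fraser complex of the basement membrane, at 220 CPM against 0 UMIs (at least 215-fold higher).

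Genes lower at 4 dpa included the antiviral gene rsad2, at 4.34 CPM against 123, a log2 ratio of −4.83 (−5.57 to −4.18), the chemokine gene cxcl12a (−4.31), crip2 (−3.50) and rgs5b (−3.09). scpp8 had 0 UMIs against 123 CPM and was at least 180-fold lower. A further group held adgrl1a, which encodes a latrophilin adhesion receptor (−5.41), ggt5b (−3.62), PEX5L (−3.56), EPB41 (−3.41) and apela, which encodes a ligand of the apelin receptor (−3.27). These 5 were most abundant in the unnamed cells of the uninjured library, at 369, 313, 227, 464 and 322 CPM. In basal-epidermal-like cells alone ggt5b and EPB41 turned to log2 ratios of 2.00 and 1.58 at 3 dpa and of 2.71 and 1.13 at 4 dpa. These turned values rest on few UMIs and are given without intervals. Within basal-epidermal-like cells the lowest genes at 4 dpa were gig2l, with 0 UMIs against 157 CPM, cxcl12a (−5.80), il4i1 (−5.77), rsad2 (−5.53), the tight junction gene cldnb (−3.25), mxb (−3.08) and the potassium channel gene kcnq5b (−3.00).

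Both cell cycle lists fixed beforehand were higher at 4 dpa in the epidermal cell set, and of the Fgf response, Wnt ligand, Wnt response and BMP lists only Wnt response lay above matched random lists. All 16 measured G2/M genes were higher at 4 dpa, with a median log2 ratio of 3.42, at percentile 100 among 10000 matched random lists. Examples were tpx2 (4.4) and ube2c (4.11), both needed for mitosis. Of 15 S phase genes 13 were higher (median 0.83), led by dut (2.42) and tyms (2.22), which act in nucleotide synthesis. Wnt response genes were higher in 3 of 4 members (median 2.04), with the transcription factor genes tcf7 (3.18) and lef1 (2.93, 63.4 CPM against 8.32), while axin2 was at −0.01. Of 9 fin fold and limb ridge factors 7 were higher (median 0.99), with dlx5a at 2.35 and dlx2a at 2.25, and msx1b was lower at −2.66. Basement membrane and hemidesmosome genes were higher in 12 of 17 members (median 1.46), with frem2a at 3.50, frem2b at 3.09 and the anchoring fibril collagen col7a1 at 2.88. Wound epidermis genes were higher in 10 of 16 (median 0.82), with the fibronectin genes fn1b (2.64, 527 CPM against 84.4) and fn1a (2.01), but over members with at least 20 CPM their median was −0.039. Higher too were keratins in 12 of 17 (median 0.71), with krt93 at 4.02 and krt94 at 2.97, and actin cytoskeleton genes in 17 of 22 (median 0.55). So were mitochondrially encoded genes in 12 of 13 (median 0.65) and glycolysis genes in 12 of 15 (median 0.40), whose median turned to −0.044 after thinning. The medians of these 10 lists and that of the SP factors (1.13) lay above the middle 95% of matched random lists.

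Stress and defence lists were lower at 4 dpa. Immediate early and heat shock genes were lower in 26 of 28 members (median −0.51, percentile 0.01 of matched random lists), with the immediate early transcription factor gene egr1 at 60.5 CPM against 290 (−2.26), junbb (−1.43) and btg2 (−1.41). Inflammatory genes were lower in 11 of 14 (median −0.64, percentile 0.04), with irg1l (−2.81), cxcl8a (−2.78) and il1b (−1.90). cxcl8a was also among the 10 leading genes of the leukocyte-like cluster 14, whose 259 cells were all from the uninjured library. Free RNA of other cells was not tested for this list. Interferon and antigen presentation genes were lower in 11 of 14 (median −0.85, percentile 0.01), with rsad2 (−4.83), mxb (−2.51) and isg15 (−1.50). Within the middle 95% of random lists were the medians of the BMP list (0.52, 6 of 8 higher), Fgf response (0.10, 4 of 8 higher, with etv5b at 2.01 and spry2 at −1.87) and Wnt ligands (−0.07, 4 of 8 higher, with wnt5b at 2.49 and wnt3 at −1.16). The desmosome and cell adhesion (−0.06), retinoic acid (−0.02) and other SP family (−0.23) medians were also within it. The Fgf ligand genes fgf16 and fgf24 had log2 ratios of 2.94 and 1.07, and the Hedgehog genes gli1 and ptch1 1.93 and 1.40.

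Basal-epidermal-like cells alone showed the same sides for most of these lists at 4 dpa. All 17 G2/M genes (median 3.50), all 5 Wnt response genes (median 3.99, lef1 at 130 CPM against 6.13), all 3 Hedgehog genes (2.71) and all 10 BMP genes (1.43) were higher, as were 15 of 19 basement membrane genes (2.05). Lower were 24 of 28 immediate early and heat shock genes (−0.52) and 12 of 14 interferon genes (−0.78). The S phase (0.71), glycolysis (0.21), Fgf response (0.14), desmosome (−0.19), retinoic acid (0.55), Wnt ligand (0.47), SP factor (1.26) and other SP (0.82) medians lay within the middle 95% of random lists, against a median of all genes of 0.35. Scaling by TMM factors moved that median by −0.34.

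**Figure D2:**
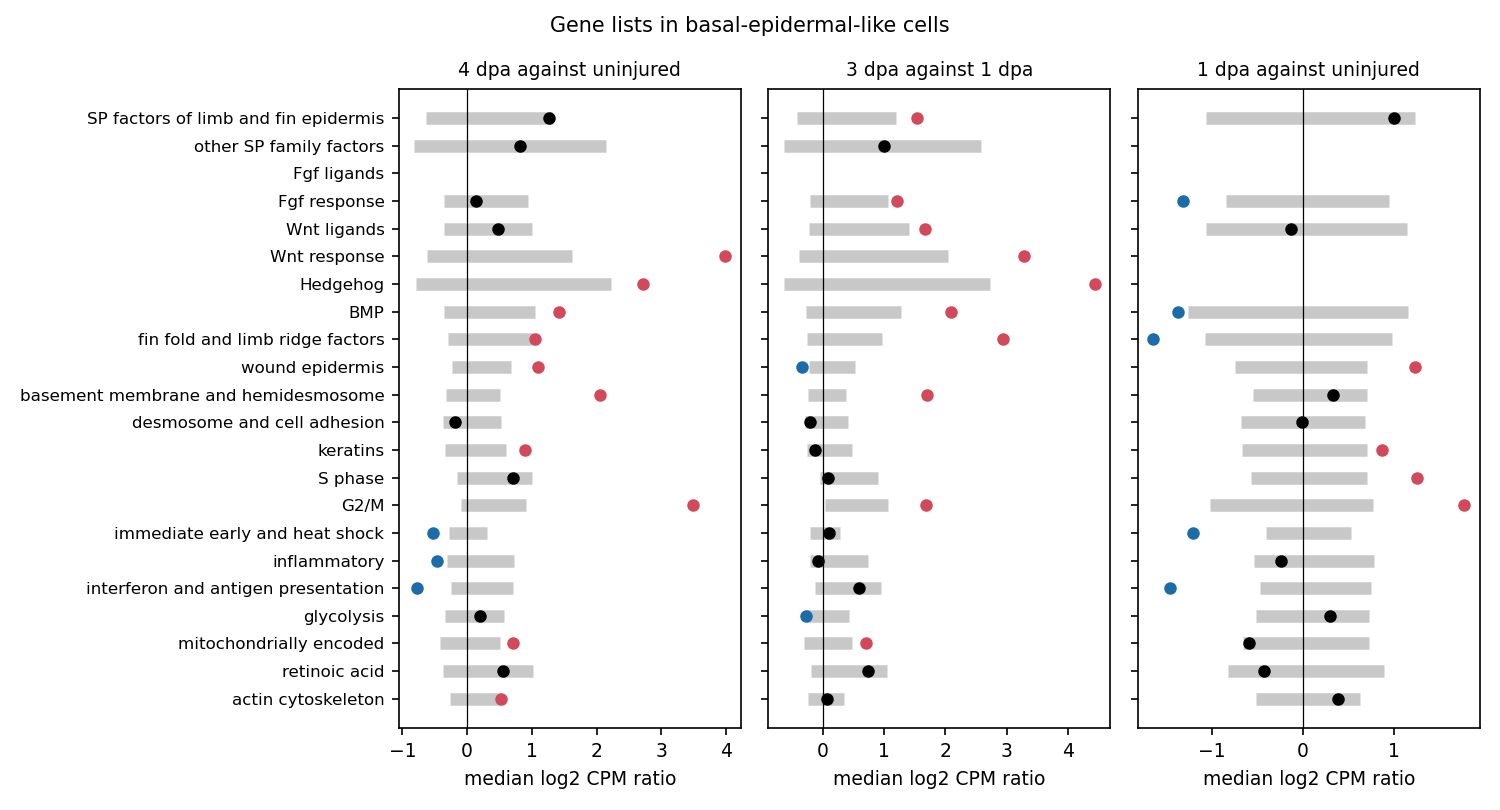
Each point is the median log2 CPM ratio of 1 fixed gene list in basal-epidermal-like cells for 4 dpa against uninjured, 3 dpa against 1 dpa and 1 dpa against uninjured, and the grey bar is the middle 95% of 10000 matched random lists. Red points lie above and blue points below that range, and the G2/M median stood at 3.50 and the immediate early and heat shock median at −0.52 in the first panel.

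The comparison of 3 dpa with 1 dpa, within batch 2, followed the epidermal cells from the early wound to the growing regenerate. The 4 highest ratios in the epidermal cell set were those of and1, at 441 CPM against 0.309 (log2 ratio 10.48, 7.997 to 15.78), col10a1a at 721 against 0.928 (9.60, 8.05 to 11.88), enam at 2052 against 4.02 (8.996, 8.22 to 9.91) and scpp7 at 149 CPM (8.91). The cytokine receptor gene cntfr and ogna were at least 123-fold and 100-fold higher. The kinesin gene kif26ba (7.67), clu (7.69), the apolipoprotein gene apoc1 (7.76) and the sialyltransferase gene st6galnac (7.38) were also higher, although over all kept cells apoc1 and st6galnac were at −0.72 and −0.98. Genes lower at 3 dpa included tpm4a, a tropomyosin gene, at 183 CPM against 1575 (−3.10, −3.21 to −3.00), and the fatty acid-binding protein gene fabp4a (−2.73). Also lower were the EGF-family growth factor gene hbegfb (−2.30), the endothelin receptor gene EDNRB (−2.04), and inhbaa, which encodes an activin subunit (−1.84), with nccrp1 at −1.83. hmox1a, which encodes heme oxygenase, was at −1.92 and rasgrp4 at −1.86, but over all kept cells they were at 0.63 and 0.66. scpp8 (−5.01) and srgn (−4.09), the gene of the granule proteoglycan serglycin, were most abundant in neutrophil-like cells, at 11399 and 7779 CPM.

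Several of these genes already differed at 2 dpa. Against 1 dpa, and1 had a log2 ratio of 9.81 at 2 dpa, col10a1a 9.08, scpp7 8.62, enam 8.39 and tpm4a −3.04, and hbegfb and inhbaa were at −1.78 and −1.74. fabp4a and scpp8 were at −1.16 and −1.39 there and fell further from 2 to 3 dpa, by −1.57 and −3.62. Of the genes with at least 50 CPM at 2 or 3 dpa that the fixed rule named, ckba (1.09) and mhc1uba, which encodes an antigen-presenting protein (1.08), rose most from 2 to 3 dpa. sp6 had a log2 ratio of 1.72 (1.46 to 2.00) at 3 dpa against 1 dpa, 2.12 (1.86 to 2.38) at 2 dpa against 1 dpa and −0.39 (−0.53 to −0.25) at 3 dpa against 2 dpa. Over the epidermal cell set sp8a was at 0.00 (−0.23 to 0.24) and sp9 at 0.23 (−0.07 to 0.54) for 3 dpa against 1 dpa, and sp8b at 0.60 (−0.02 to 1.24). In basal-epidermal-like cells alone sp6 was at 2.13 (1.80 to 2.47), sp8a at 2.15 (1.57 to 2.77), sp9 at 0.95 and sp8b at 0.46, with enam at 8.85, tpm4a at −3.16 and hbegfb at −2.90. krt1-19e was at 1.00 and krt4 at −1.14 in the epidermal cell set, and at 0.81 and −2.03 in basal-epidermal-like cells.

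Fin fold, Fgf response, BMP and Wnt lists were higher at 3 dpa than at 1 dpa in the epidermal cell set. All 9 fin fold and limb ridge factors were higher (median 2.82), with dlx5a at 3.28 and dlx4a at 3.04. So were all 8 Fgf response genes (1.12), with the ETS factor genes etv4 (3.90, 59.9 CPM against 4.02) and etv5b (2.97). All 7 BMP genes (1.39), with id2b at 3.34 and smad6b at 2.49, and all 3 Wnt response genes (3.40), with lef1 at 3.62 and tcf7 at 3.04, were higher too. Of 8 Wnt ligand genes 7 were higher (1.08), with wnt5b at 2.31 and wnt3 at 1.60. Of 17 basement membrane genes 12 were higher (1.78), with frem2a at 5.32 and fras1 at 3.56. All 18 G2/M genes were higher (1.31), with ccnb1 at 3.15, while 12 of 16 S phase genes were lower (−0.28), with gins2 at −0.91, a median that turned to 0.012 after thinning and to 0.018 with equal weight per cell. Mitochondrially encoded genes were higher in 9 of 12 (0.73), with mt-nd3 at 1.67, and retinoic acid genes in 10 of 12 (0.63), with dhrs3b at 3.94 and stra6 at 2.27. Wound epidermis genes (−0.21, 9 of 16 lower) and desmosome genes (−0.32, 14 of 17 lower, with pkp1b at −1.25) had medians below the middle 95% of random lists. Over all kept cells the desmosome median turned to 1.00 and the mitochondrially encoded median to −0.23. Within that range were the medians of the SP factors (0.42), other SP genes (0.95), keratins (0.17), immediate early and heat shock genes (0.11), inflammatory genes (−0.07), interferon genes (0.44), glycolysis (−0.07) and actin genes (0.06). fgf24 was at 0.88 and gli1 at 4.60. The median of all genes was 0.27, and TMM and DESeq2 scaling moved it by −0.31 and −0.35.

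Basal-epidermal-like cells alone gave medians above the middle 95% of random lists at 3 dpa against 1 dpa, at 2.94 for fin fold factors, 1.21 for Fgf response, 2.08 for BMP and 3.27 for Wnt response, and also for the SP factors (1.54) and Hedgehog genes (4.43). Their S phase median of 0.09 was within the range of random lists.

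The comparison of each regenerating library with the uninjured library described the time course from intact fin, but batch and time cannot be told apart at 1, 2 and 3 dpa, and all 4 ratios share 1 uninjured library. Among the genes higher at all 4 times in the epidermal cell set were, with log2 ratios at 1, 2, 3 and 4 dpa, adam8a (9.57, 10.26, 9.77 and 8.03), fabp4a (10.73, 9.57, 8.0 and 3.91) and fstl1a, which encodes a follistatin-like secreted protein (4.99, 8.54, 7.96 and 7.05). So were the fibronectin receptor gene itga5 (3.48, 4.15, 4.14 and 3.47), krt93 (4.14, 3.96, 3.51 and 4.02) and the proliferation gene mki67 (3.05, 3.26, 3.75 and 3.25). sp6 was at 3.67 (3.05 to 4.34), 5.78 (5.21 to 6.42), 5.39 (4.82 to 6.03) and 4.19. sp9 was at 2.00, 2.15, 2.24 and 1.23, sp8b at 1.37 (−0.41 after thinning and over all kept cells), 2.497, 1.97 and 0.98, and sp8a at 0.89, 0.91, 0.89 and 1.02. The thinned sp8b value rests on few UMIs and does not settle the direction. Another random thinning to 1000 UMIs found sp8b in 8 of 841 cells at 1 dpa against 2 of 847 uninjured. krt1-19e was at −1.20, −0.62, −0.20 and −0.06. Among the genes lower at all 4 times, adgrl1a (−8.29, −8.07, −6.92 and −5.41), the transcription factor gene ebf1b (−5.88, −6.34, −10.09 and −2.92) and chgb, which encodes a secretory granule protein (−6.74, −7.94, −5.79 and −2.75), were leading or abundant genes of the unnamed cells. In basal-epidermal-like cells chgb turned to 1.19 at 1 dpa and 1.00 at 3 dpa and adgrl1a to 0.41 at 3 dpa, as lower bounds. rsad2 was at −3.73, −3.20, −2.73 and −4.83.

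Some genes stood highest at 1 dpa. tpm4a stood at 1575 CPM against 26.9 in the uninjured library (5.87), fn1a at 484 against 21.95 (4.46), fn1b at 1649 against 84.4 (4.29) and EDNRB had a log2 ratio of 4.99. Of the fixed lists, G2/M genes were higher at every time (medians 2.79, 3.26, 3.74 and 3.42), with cdk1 at 3.68 at 1 dpa. So were S phase genes (2.07, 1.37, 1.90 and 0.83), keratins (0.77, or −0.46 over all kept cells, then 0.69, 1.07 and 0.71), actin genes (0.66, 0.47, 0.52 and 0.55) and the SP factors (1.69, 2.33, 2.1 and 1.13). Immediate early and heat shock genes were lower at every time, with 0 of 28 members higher at 1, 2 or 3 dpa (medians −1.20, −1.27 and −1.19). The heat shock gene hsp70l stood at 7308 CPM in the uninjured library against 1471, 1510 and 1583. Interferon genes were also lower (−1.22, −0.80 and −0.81), with irf7 at −2.44 at 1 dpa. The fin fold (−1.35, 0.72 and 1.17), BMP (−0.74, 0.61 and 0.57) and Fgf response (−1.32, −0.20 and −0.10) medians were lowest at 1 dpa, with msx1b at −3.43, id2b at −2.73 and dusp6 at −1.54 there. The Wnt response median stood at 2.88 and 3.42 at 2 and 3 dpa.

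Basement membrane genes (0.31, 1.64 and 2.19 at 1, 2 and 3 dpa) and wound epidermis genes (0.26, 1.44 and 1.24) lay above the middle 95% of random lists at 2 and 3 dpa and within it at 1 dpa. Mitochondrially encoded genes lay below it at 1 and 3 dpa (−0.81, or 0.37 over all kept cells, and −0.70) and were at −0.04 at 2 dpa. The retinoic acid medians were −0.82, −0.53 and 0.27, the inflammatory medians −0.18, −0.18 and 0.00, and the glycolysis medians 0.19, −0.11 and 0.01. The desmosome medians were 0.33, 0.12 and 0.15, the Wnt ligand medians 0.04, 0.57 and 0.42, and the other SP medians −0.65, −0.06 and 0.23. Scaling by TMM moved the median of all genes by 0.24 at 1 dpa and 0.12 at 2 dpa. The Hedgehog genes gli1 and ptch1 were at 1.75 and 1.47 at 2 dpa and at 2.61 and 2.42 at 3 dpa, and fgf24 was at −0.21, 0.74 and 0.68.

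In basal-epidermal-like cells alone adam8a (9.07, 9.67, 9.21 and 7.92), the ephrin receptor gene epha4a (4.39, 5.77, 5.25 and 5.13), the planar polarity gene prickle1a (4.41, 4.30, 4.23 and 4.72) and eda, which encodes the ligand ectodysplasin and had 0 UMIs in the uninjured library (at least 31.4-, 34.0-, 49.8- and 65.5-fold higher), were among the genes higher at all 4 times. krt4 was also higher in them (9.69, 8.65, 7.66 and 5.81), from 6.13 CPM in the uninjured library to 5052 CPM at 1 dpa. Lower were cxcl12a (−5.32, −4.33, −4.20 and −5.80), kcnq5b (−4.77, −4.41, −4.04 and −3.00), the mTOR regulator gene deptor (−3.90, −3.85, −3.45 and −2.65) and msx1b (−4.33, −5.24, −3.05 and −2.52). sp6 was at 4.19 (3.14 to 5.44), 6.69 (5.70 to 7.91), 6.31 (5.32 to 7.53) and 5.72.

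**Figure D3:**
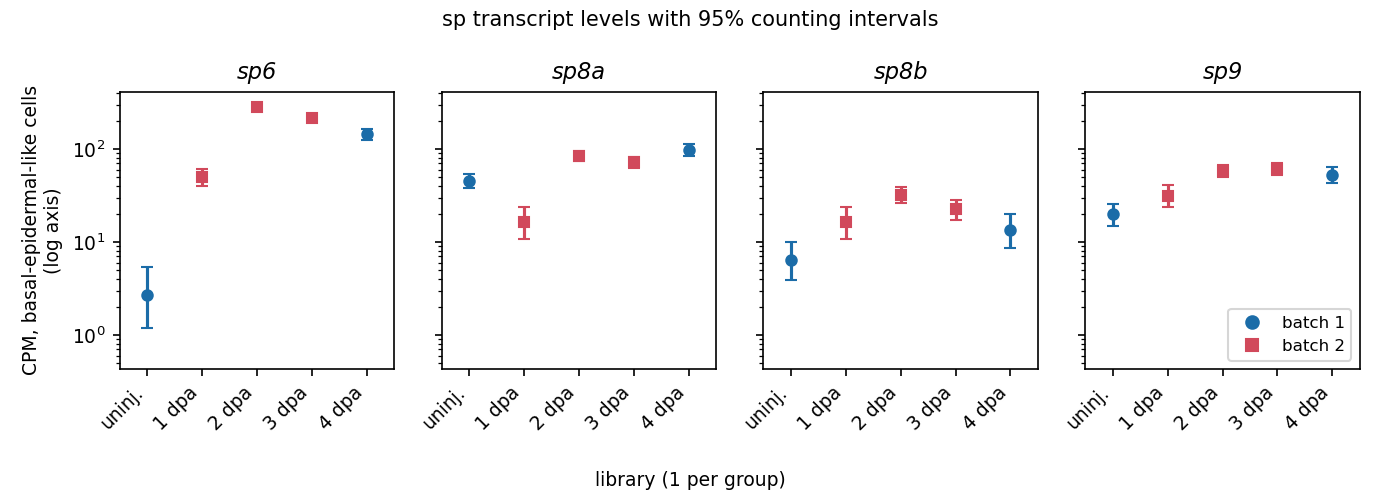
Levels of sp6, sp8a, sp8b and sp9 in basal-epidermal-like cells are plotted in CPM on a log axis for each library, with exact Poisson 95% intervals as bars, circles for batch 1 and squares for batch 2. sp6 stood at 2.72 CPM in the uninjured library and at 49.6, 281, 216 and 143 CPM at 1, 2, 3 and 4 dpa.

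The share of cells with an sp transcript was compared at equal depth, with each cell thinned to 1000 UMIs, because the study concerns these epidermal factors. sp6 was found in 0.354% of the uninjured epidermal cell set (exact 95% interval 0.073 to 1.03), 4.4% at 1 dpa (3.12 to 6.01), 12.7% at 2 dpa (10.8 to 14.7), 10.6% at 3 dpa (9.07 to 12.4) and 4.74% at 4 dpa (3.03 to 7.03). sp8a was found in 3.78% (2.60 to 5.29), 5.23%, 6.64%, 7.17% and 8.04% (5.78 to 10.8), sp9 in 0.590%, 3.81%, 4.09%, 5.43% and 2.89%, and sp8b in 0.236%, 0.951%, 2.55%, 1.67% and 0.825%. In leukocyte-like cells, which should lack these genes, sp6 was found in 0 of 361, 1626, 1112, 1322 and 1276 cells, with upper bounds of 1.02%, 0.227%, 0.331%, 0.279% and 0.289%. Median depths before thinning were 4856, 3043, 4079, 2968 and 6532 UMIs in the epidermal cell set and 8254, 3044.5, 3390, 2643.5 and 9652 in leukocyte-like cells. Without thinning the sp6 shares were 2.25% (1.42 to 3.39), 10.6%, 25.8%, 17.8% and 13.3%. Leukocyte-like cells then had an sp6 UMI in 1 of 408 cells of the uninjured library (0.245%, 0.006 to 1.36), at a median of 7565 UMIs against 3749.5, and in 0 of 1756, 1173, 1447 and 1303 cells of the others.

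sp8a and sp6 stood at different levels in the epidermal clusters. In cluster 7, named superficial-epidermal-like with the limit given above, sp8a stood at 63.7 CPM in the uninjured library and at 348, 151, 187 and 141 CPM at 1, 2, 3 and 4 dpa, against 45.3, 16.3, 83.7, 72.3 and 97.51 CPM in basal-epidermal-like cells. sp6 in cluster 7 stood at 2.27, 4.77, 5.2, 3.98 and 7.49 CPM. In intermediate-epidermal-like cells sp6 stood at 13.6, 52.7, 88.0, 57.8 and 25.9 CPM. Several of these sp6 levels rest on few cells and are given without intervals. Without thinning, sp6 was found in 4, 2, 3, 2 and 7 cells of cluster 7 from uninjured to 4 dpa. Of the intermediate-epidermal-like cells it was found in 8 of 58 in the uninjured library and 4 of 16 at 4 dpa.

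Cells with an sp8a or sp8b UMI were compared with equal numbers of cells without one, drawn from the same library and UMI decile, to ask what sp8 cells shared across the time course. Of the genes named by the fixed rule, the homeobox gene msx2b rose most in sp8-detected cells, with a log2 fold change of 2.48 (SE 0.24, adjusted p = 0.00063 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That of dlx5a was 1.94 (SE 0.17) and that of unc5b, a netrin receptor gene, 1.88 (SE 0.23). The BMP antagonist gene bambia had 1.53 (SE 0.24), fras1 1.35 (SE 0.18) and wnt5b 1.25 (SE 0.22). Each of these 6 was higher in 5 of 5 libraries, but the naming rule required 1 direction in every library. vipr1b (1.88), myoc (1.80), sorcs2 (1.61) and si:ch211-217k17.9 (0.98) also rose in 5 of 5. Those that fell most were grna.2 (−8.95, SE 0.98), si:ch73-343g19.4 (−7.33), si:ch73-359m17.7 (−7.13), si:ch73-359m17.9 (−6.53) and si:ch211-198m17.1 (−6.51). They were followed by the NADPH oxidase subunit gene ncf1 (−6.41, 1.94 CPM against 138), chia.6 (−6.27), the transcription factor gene spi1a (−6.10), the macrophage marker lcp1 (−5.98) and fermt3b (−5.74). Those fell together with 52 and 59 unnamed cells in the matched arms of the uninjured and 4 dpa libraries against 1 and 2 in the sp8-detected arms, and grna.2, si:ch73-359m17.7, si:ch73-359m17.9 and si:ch73-343g19.4 led 1 of the unnamed clusters.

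Of the fixed lists in the sp8 contrast, 4 of 9 tested fin fold factors rose (dlx4a, dlx5a, msx2a and msx2b), and 8 adjusted over the list alone. wnt5b of 6 Wnt ligands and tcf7 of 3 Wnt response genes rose, as did fras1 and frem3 of 17 basement membrane genes, with 5 adjusted over the list alone. Of 16 keratins krt18a.1 and krt97 rose and krt18b fell, with 7 past the threshold adjusted over the list alone. Of 21 actin genes 4 fell (actb1, pfn1, cfl1 and arpc1b) and 9 adjusted over the list alone, and eno1a of 15 glycolysis genes and rarab of 10 retinoic acid genes fell, with 3 and 1 adjusted over the list alone. In the other 14 lists edgeR called 0 of 153 tested members, 26 had an unadjusted p under 0.05, and DESeq2 called 3 (sp6, cldne and klf2a). Adjusted over the list alone, sp6 and sp9, fgf24, 4 of 8 Fgf response genes (dusp6, etv4, etv5a and etv5b), 3 of 6 BMP genes (id2a, id3 and smad7) and klf2a of 27 immediate early genes rose. None of the other SP, Hedgehog, wound epidermis, desmosome, S phase, G2/M, inflammatory, interferon or mitochondrially encoded members passed.

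In all, 28 genes were higher and 121 lower in sp8-detected cells among 8897 tested, with 1275 at an unadjusted p under 0.05. In basal-epidermal-like cells alone the counts were 162 and 76, and with no library block 0 and 0. Without 1 library the counts were 10 and 102 (without 2 dpa), 11 and 95 (without 3 dpa), 12 and 75 (without 4 dpa) and 18 and 84 (without uninjured). With matching within clusters edgeR called 1 gene higher and 1 lower, with 519 of 7498 genes at an unadjusted p under 0.05. Of 16 ways to assign the arms within libraries, 2 called as many genes, the real one included. The gene higher was cxcr4a, of a chemokine receptor (0.90, SE 0.11, adjusted p = 0.00139 by edgeR's quasi-likelihood test). It was higher in 5 of 5 libraries, as the naming rule required. The gene lower was scpp7 (−2.43, SE 0.26, lower in 4 of 5 libraries and named after its value was seen). Adjusted over the list alone, 7 of 7 tested fin fold factors (median 0.64), 5 of 5 BMP genes (0.44), sp6 and sp9, wnt5b, lama5, fras1, atf3 and ptgs2a rose, and krt91, il1b, rbp4 and pfn1 fell. Of the members that passed with the first matching, fgf24, the 4 Fgf response genes, tcf7, col7a1, frem2b, frem3, klf2a, all 7 keratins, eno1a, ldha and 8 of the 9 actin genes did not, and msx2a, pfkpb and rarab were not tested. In that fit the counts were 4 and 3 without uninjured, 0 and 1 without 1 dpa (507 at an unadjusted p under 0.05), 6 and 3 without 2 dpa, and 1 and 2 without 4 dpa. DESeq2 was run with the first matching only and called 61 higher and 149 lower.

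Cells with an sp6 UMI were compared in the same way. Of the genes named by the fixed rule, col14a1a, a fibril-associated collagen gene, rose most, with a log2 fold change of 4.20 (SE 0.29, adjusted p = 0.00137 by edgeR's quasi-likelihood test, 178 CPM against 9.75). That of timp2b, a metalloprotease inhibitor gene, was 3.82 (SE 0.86), wnt5b 2.83 (SE 0.33), dlx5a 2.82 (SE 0.24), and adam8a 2.77 (SE 0.35). The planar polarity gene prickle1b had 2.67 (SE 0.24), egfl6 2.65 (SE 0.23), col1a1a 2.51 (SE 0.38), fras1 2.40 (SE 0.26) and col7a1 2.39 (SE 0.30). Each of these 10 was higher in 5 of 5 libraries, but the naming rule required 1 direction in every library. The genes that fell most included prkcz, a polarity kinase gene (−3.50, SE 0.30), ugt5f1 (−3.26, SE 0.54), mctp2b (−3.10) and tprg1 (−2.50), each lower in 5 of 5. ugt5f1 was also among the leading genes of the superficial-epidermal-like cluster, whose cells made up 25 of the matched cells at 4 dpa against 7 of the sp6-detected cells.

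Of the fixed lists in the sp6 contrast, 5 of 6 tested fin fold factors rose (dlx2a, dlx2b, dlx4a, dlx5a and and1), 7 of 16 basement membrane genes (among them col7a1, fras1, frem2b and HSPG2) and 5 of 13 wound epidermis genes (fn1a, fn1b, mmp9, mmp14a and timp2b). So did etv4 and etv5b of 6 Fgf response genes, wnt5b and wls of 4 Wnt ligand genes, lef1, the 1 Wnt response gene tested, smad6b of 5 BMP genes and cyp26a1, which degrades retinoic acid, of 7 retinoic acid genes. Adjusted over the list alone the numbers that rose were 5, 11, 5, 4, 3, 1, 2 and 1, in the same order, and 1 basement membrane gene and 1 retinoic acid gene fell. Of 27 immediate early genes 4 fell (fosab, jun, dusp1 and klf2b), and 6 adjusted over the list alone. Of 16 desmosome genes pkp3b rose and ppl, evpla and cldne fell. Of 15 keratins krt18a.1 and krt96 rose and krt17, krt18b and krt1-19e fell. Among those that fell, ppl, evpla, cldne and krt17 are also superficial epidermal markers. From uninjured to 4 dpa the matched arms held 5, 13, 52, 32 and 25 superficial-epidermal-like cells against 4, 2, 3, 2 and 7 detected. Adjusted over the list alone 6 desmosome genes and 7 keratins passed. pfn1 and arpc1b of 19 actin genes fell, with 2 higher and 6 lower adjusted over the list alone. In the other 8 lists edgeR called 0 of 80 tested members, 20 had an unadjusted p under 0.05, and DESeq2 called 1 (sp9). Adjusted over the list alone sp8a, sp8b and sp9 rose and 6 of 14 S phase genes fell. None of the other SP, G2/M, inflammatory, interferon, glycolysis or mitochondrially encoded members passed.

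In all, 267 genes were higher and 237 lower in sp6-detected cells among 6556 tested, with 1641 at an unadjusted p under 0.05, and 25 genes were called in the same direction in the sp6 and sp8 contrasts. In basal-epidermal-like cells alone, over 4 libraries, the sp6 counts were 739 and 653, and with no library block 0 and 0. The uninjured library gave only 22 sp6-detected cells, at a median of 17764 UMIs against 19406.5 in the matched cells. Without it the counts were 724 and 712, and they were 243 and 129 without 1 dpa, 23 and 17 without 2 dpa, 13 and 19 without 3 dpa and 105 and 56 without 4 dpa. Matching within clusters used 206 of the 340 sp6-detected cells at 2 dpa, 208 of 307 at 3 dpa and 33 of 71 at 4 dpa. With that matching edgeR called 3 genes higher and 4 lower. Higher were sema5ba, a semaphorin gene (1.51, SE 0.21), bcl2l10, an apoptosis regulator gene (0.80, SE 0.11), and fabp4a, named after its value was seen (1.99, SE 0.26, higher in 3 of 5 libraries). Lower were zgc:136930 (−1.24, SE 0.12), si:dkey-183i3.5 (−0.98, SE 0.10), krt1-19e (−0.97, SE 0.14) and rbp4 (−0.89, SE 0.11). Except fabp4a, each went the same way in 5 of 5 libraries, as the naming rule required. Adjusted over the list alone, dlx5a, wnt5b, etv4, krt8, krt93 and krt94 rose, and col17a1a, itgb4, krt5, krt15, krt1-19e, rbp4 and pfn1 fell. None of the tested SP, BMP, Wnt response, wound epidermis, desmosome, S phase or immediate early members passed, and no basement membrane gene rose, although members of each of these lists had passed with the first matching. In that fit the counts were 4 and 6 without uninjured, 0 and 2 without 1 dpa, 0 and 4 without 2 dpa, 0 and 2 without 3 dpa, and 12 and 4 without 4 dpa. edgeR called 0 genes higher without 1, 2 or 3 dpa, where 246, 216 and 205 genes had an unadjusted p under 0.05. DESeq2 was run with the first matching only and called 269 higher and 236 lower.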

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

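The tests for the pattern of sp6 and of sp-detected cells, and the batch test for the stress genes, were chosen only after their results had been seen, while the test of the stress genes in leukocyte-like cells was written before its result.

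EGFP, a feature outside the comparisons and the product of the krt4:LY-EGFP transgene whose green cells the sort excluded per the labels, was counted above the level in leukocyte-like cells of the uninjured library (0.333 CPM). It stood at 172 CPM in the mesenchymal-like cells of the uninjured library, where 51.3% of cells had an EGFP UMI and krt4 stood at 4026 CPM. In cluster 7, named superficial-epidermal-like, it stood at 212 CPM at 1 dpa, 119.6 CPM at 2 dpa and 89.5 CPM at 3 dpa, and at 4 dpa the highest level was 10.8 CPM in osteoblast-like cells. Levels in other classes are not listed here. The leukocyte-like level of the uninjured library does not give the background of the regenerating libraries, so their levels cannot be read as above background from it.

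In basal-epidermal-like cells sp8a went opposite ways by time, with log2 ratios to uninjured of −1.47 at 1 dpa and 0.89, 0.68 and 1.11 at 2, 3 and 4 dpa. The BMP list median was 1.43 at 4 dpa and −1.37 at 1 dpa, and that of the fin fold and limb ridge factors 1.06 and −1.64. The mitochondrially encoded median was 0.71 at 4 dpa and −0.70 at 3 dpa. These differences between times were not tested, since each time has 1 library. The times on opposite sides were also of different batches for the 3 lists. For BMP and fin fold the labelled batch as the whole cause is argued against, since within batch 2 their medians for 3 dpa against 1 dpa were 2.08 and 2.94, above the middle 95% of random lists (upper ends 1.27 and 0.97). For mitochondrially encoded genes batch and time cannot be told apart between 3 and 4 dpa.

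sp6 was higher in basal-epidermal-like cells of all 4 regenerating libraries than in the uninjured library. Depth per cell is argued against, because at 1000 UMIs a cell the lowest lower bound of the regenerating shares was 2.58% and the uninjured upper bound was 2.08%. Free RNA is argued against by the leukocyte-like cells of the 4 regenerating libraries, which held 0 sp6 UMIs, a level of 0.114 CPM if set to 3 counts, against a lowest basal-epidermal-like level of 49.6 CPM. At 4 dpa, in the batch of the uninjured library, the log2 ratio had a lower bound of 4.72, which the labelled batch cannot give, but for the other 3 libraries (1, 2 and 3 dpa) batch and time cannot be told apart, since no uninjured library shares their batch. Amputation itself may account for the difference, as may the fin region sampled, and neither was tested against the other.

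Immediate early and heat shock genes were lower in basal-epidermal-like cells of all 4 regenerating libraries than in the uninjured library. The labelled batch as the whole cause is argued against by 4 dpa, in the same batch, where the list median was −0.52 and the lower end of the middle 95% of random lists was −0.28. In leukocyte-like cells the list was also lower at all 4 times, with −0.69 as the median nearest to 0 (also without cluster 20, which had an osteoblast marker among its leading genes), so handling of the uninjured library's cells as a whole, in dissociation, sorting or loading, is a candidate explanation. A biological difference between intact and regenerating fin that reaches several cell types would give the same values and stays open.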

How the results depend on the processing

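The alternatives that combine basal-epidermal-like cells with another setting, or with matching within clusters, each library left out of the cluster-matched fits, no filter on genes in the libraries of the basal-epidermal-like fits, leukocyte-like cells without cluster 20 and mesenchymal-like cells alone, were added after the data were seen, and the others were planned. No paired analysis was possible for the comparisons between groups because each has 1 library, and the sp8 and sp6 contrasts were paired by the library block. Depth limits what can be told apart where a gene has few UMIs, and the intervals do not cover differences between animals. The sp6 ratios kept their direction under every alternative run. For the epidermal cell set they ranged from 2.67 to 5.72 (4 dpa against uninjured), 1.37 to 3.23 (3 dpa against 1 dpa), 1.78 to 4.19 (1 dpa), 5.06 to 6.69 (2 dpa) and 5.01 to 6.31 (3 dpa against uninjured). Of 1085 list medians of the epidermal cell set under alternatives 9 reversed and 111 moved, and of 904 in basal-epidermal-like cells 1 and 84. Of 1214 ratios of other named genes in the epidermal cell set 24 reversed and 393 moved, and of 952 in basal-epidermal-like cells 1 and 216. Of 150 class shares 11 moved, and a share has no direction that could reverse. With DESeq2 all 40 named genes of the contrasts stayed past the threshold, and with matching within clusters none of the 23 still tested did. With no library block 0 of the 40 did, and with another draw of matched cells 34 did and 4 did not. With a library left out, 3 (without uninjured) to 13 (without 2 dpa) did not, genes named from the cluster-matched fits included. Where a cause is not given below, the cause was not tested.

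Over all kept cells, which adds leukocyte-, mesenchymal- and osteoblast-like cells by construction, the sp6 ratio was 2.67 at 4 dpa, 1.78 at 1 dpa and 5.06 at 2 dpa against uninjured and 3.23 for 3 dpa against 1 dpa. Reversed were sp8a (−0.44) and krt4 (−0.81) at 4 dpa, sp8b (−0.41) and krt4 (−0.10) at 1 dpa against uninjured, and apoc1 (−0.72), st6galnac (−0.98), hmox1a (0.63) and rasgrp4 (0.66) for 3 dpa against 1 dpa. The desmosome list (1.00) and the mitochondrially encoded list (−0.23) reversed for 3 dpa against 1 dpa, and the keratins (−0.46) and mitochondrially encoded genes (0.37) at 1 dpa against uninjured.

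In basal-epidermal-like cells, which leave out the unnamed cells by construction, the sp6 ratio was 5.72, 6.69 and 6.31 at 4, 2 and 3 dpa against uninjured and 2.13 for 3 dpa against 1 dpa. Against uninjured, ggt5b reversed at 4, 1, 2 and 3 dpa (2.71, 2.36, 1.45 and 2.00), EPB41 at 4, 1 and 3 dpa (1.13, 0.19 and 1.58), PEX5L at 2 and 3 dpa (1.09 and 1.41), crip2 at 2 dpa (2.87), rgs5b at 1 and 2 dpa (0.78 and 0.13), chgb at 1 and 3 dpa (1.19 and 1.00) and adgrl1a at 3 dpa (0.41). The values for PEX5L, chgb and adgrl1a are lower bounds, and those for ggt5b and EPB41 rest on few UMIs. The S phase list reversed for 3 dpa against 1 dpa (0.092). sp8a at 1 dpa against uninjured also changed sign, to −1.47, but was not counted as reversed because its main ratio was under 1.

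For 3 dpa against 1 dpa the sp6 ratio was 1.41 with TMM and 1.37 with DESeq2 scaling in the epidermal cell set, and in basal-epidermal-like cells 1.79 with TMM scaling, 1.72 with DESeq2 scaling and 1.68 after thinning. Thinning also reversed sp8b at 1 dpa (−0.41) and, in basal-epidermal-like cells, at 4 dpa (−0.24), the glycolysis list at 4 dpa (−0.044), the S phase list for 3 dpa against 1 dpa (0.012) and the Wnt response list of basal-epidermal-like cells at 2 dpa (−0.044). The sp8b reversals rest on few UMIs. Another random thinning to the same depth found sp8b in 0.951% of the epidermal cell set at 1 dpa against 0.236% uninjured. In basal-epidermal-like cells it found sp8b in 0.962% at 4 dpa against 0.377% uninjured. Equal weight per cell reversed the S phase list for 3 dpa against 1 dpa (0.018), and keeping only members with at least 20 CPM reversed the wound epidermis list at 4 dpa (−0.039). For the basal-epidermal-like cells, TMM and DESeq2 scaling moved the median of all genes by −0.34 and −0.35 at 4 dpa, −0.41 and −0.53 at 3 dpa and −0.24 and −0.38 at 2 dpa against uninjured, and by −0.34 and −0.41 for 3 dpa against 1 dpa. For the epidermal cell set DESeq2 scaling moved it by 0.27 at 1 dpa against uninjured, and the ratio of 3 dpa to 2 dpa moved by −0.19 with TMM.

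The sp6 shares without thinning were 2.25%, 10.6%, 25.8%, 17.8% and 13.3% from uninjured to 4 dpa, and after thinning to 2000 UMIs 7.12%, 19.5%, 17.1% and 8.87% at 1 to 4 dpa. These settings change both the UMIs per cell and the cells kept, and the parts cannot be told apart here. Thinning to 2000 UMIs left out 391, 382, 732 and 128 cells at 1 to 4 dpa. In basal-epidermal-like cells thinned to 1000 UMIs the sp6 shares were 17.9%, 14.9% and 10.6% at 2, 3 and 4 dpa.

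For sp8-detected cells, DESeq2 called 61 genes higher. Without a filter on genes edgeR tested 23257 genes and called 420 higher and 746 lower. With no library block it called 0 higher and 0 lower, with 440 at an unadjusted p under 0.05. With matching within clusters it called 1 and 1, in basal-epidermal-like cells 162 and 76, and with both 0 and 1, with 426 at an unadjusted p under 0.05. Leaving out each library gave 10 to 32 higher and 75 to 125 lower. For sp6-detected cells the counts were 884 and 866 without a filter, 0 and 0 with no block (619 at an unadjusted p under 0.05), 3 and 4 with matching within clusters, 739 and 653 in basal-epidermal-like cells, where the uninjured library had too few cells, 7 and 8 with both, and 13 to 724 higher and 17 to 712 lower with each library left out, the highest of these without uninjured and the lowest without 3 dpa (higher) and 2 dpa (lower). DESeq2 with the block called 61 and 149 for sp8 and 269 and 236 for sp6. With both restrictions on sp6, bambia (1.41) and krt97 (0.77) were higher. Among those lower were ptgdsb.2 (−2.26), lgals1l1 (−1.82), col17a1a (−1.16), krt1-19e (−1.07) and pfn1 (−0.43). Each went 1 way in 4 of 4 libraries, as the naming rule required.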

Other observations

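The tests and cell sets in this part were chosen after the results they concern were seen.

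Leukocyte-like cells, which the report's ratios leave out, also differed between libraries in cell cycle and defence genes. Cluster 20 was left out here, because its leading genes held spp1 of the osteoblast marker set and no gene of the leukocyte marker sets. They also held acp5a, ctsk and tyrobp, and 3 macrophage or dendritic markers were raised in that cluster. Leaving it out therefore does not show that its cells were not leukocytes. From 1 to 3 dpa, within batch 2, all 10 measured S phase genes (median log2 ratio 3.31), all 15 G2/M genes (2.70) and all 13 interferon and antigen presentation genes (1.44) were higher, and 24 of 25 immediate early and heat shock genes were higher (1.02). At 4 dpa against uninjured, within batch 1, all 15 G2/M genes were higher (0.62), while 12 of 13 inflammatory genes (−0.96), 11 of 14 interferon genes (−0.55) and 5 of 6 Fgf response genes (−0.85) were lower. Different clusters held most of these cells in different libraries. Of cluster 1, 1384 of 1396 cells were from 1 dpa, of cluster 2, 1041 of 1096 cells from 4 dpa, and of cluster 14, led by cxcl8a and cd8b, 259 of 259 cells from the uninjured library. Clusters 2 and 14 were named macrophage- or dendritic-like, but their 10 leading genes held the lymphocyte marker cd8a and no macrophage or dendritic marker. The other clusters so named had no macrophage or dendritic marker among their leading genes either. Leading genes were ranked against all other kept cells, clusters of the same name included, so markers that these clusters share can be missing there.

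Mesenchymal-like and osteoblast-like cells, pooled, had G2/M medians of 3.72 at 4 dpa against uninjured and 1.86 at 3 dpa against 1 dpa, but their mix differed, with 195 mesenchymal-like and 12 osteoblast-like cells in the uninjured library, 1143 and 694 at 1 dpa, 115 and 226 at 3 dpa, and 85 and 116 at 4 dpa. In mesenchymal-like cells alone only 1 G2/M gene was measured at 4 dpa against uninjured, and 11 of 14 were lower at 3 dpa against 1 dpa (−0.30, within the middle 95% of random lists). The fin fold and limb ridge median of 1.51 at 4 dpa in the pooled cells was 0.17 in mesenchymal-like cells alone, also within that range. In them all 25 immediate early and heat shock genes (−1.23) and 7 of 8 keratins (−2.42) were lower at 4 dpa. Higher were 13 of 20 actin genes (0.86), 8 of 10 interferon genes (1.43) and 9 of 15 wound epidermis genes (1.07). From 1 to 3 dpa all 16 S phase genes (−2.50) and 12 of 15 glycolysis genes (−0.99) were lower. Higher were 8 of 9 keratins (2.81), 25 of 26 immediate early and heat shock genes (1.49), all 8 interferon genes (1.73), 10 of 13 retinoic acid genes (1.15) and 11 of 16 wound epidermis genes (0.64), while the fin fold median (0.81, all 9 higher) lay within the middle 95%. Of the 195 mesenchymal-like cells of the uninjured library 193 formed a cluster of their own led by gyg1b, frzb and POSTN, and 959 of 966 cells of a cluster led by tph1b and crabp2b were from 1 dpa. In the cluster of those 193 cells 4 of 8 mesenchymal markers were raised, and none was among its 10 leading genes. The mesenchymal-like cells of the uninjured library also held krt4 and EGFP transcripts, as given above. Their name is thus uncertain, and the lower keratins at 4 dpa may not be a change within 1 cell type.

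Genes differed between sp6- or sp8-detected cells and cells of the same UMI decile. Whether cells of other classes in the matched arm gave the differences was tested over all called genes, in the same libraries and with no filter on genes. With both arms basal-epidermal-like, 0.0 of the median log2 fold change of the 121 genes lower in sp8-detected cells was kept (−3.85 before), with 32 at 0 UMIs, 35 still lower and 54 higher. Cells of other classes are therefore a candidate explanation for those genes. For the 28 genes higher 0.766 was kept (1.63 and 1.25, 95% interval over genes 0.671 to 0.900). For sp6, in 4 libraries, 0.753 was kept for the 267 genes higher (0.702 to 0.791) and 0.567 for the 237 lower (0.407 to 0.737). These 3 values lie between what a mixture of classes as the main cause and its absence would give. Direction was kept by 27 of the 28 genes higher for sp8 and by 265 of the 267 for sp6. Of the 237 genes lower for sp6, 158 kept it and 54 turned. With matching within clusters 0.200 was kept for sp6 (1.26 and 0.25, 3 of 399 called again) and 0.168 for sp8 (1.62 and 0.27, 0 of 58 called again by edgeR). The clusters were made from genes that include 180 of the 504 called for sp6 and 58 of the 149 called for sp8, so part of this loss was built in, and whether sp6 and sp8 transcripts only mark clusters stays open. For sp6 that matching also used fewer detected cells, so the fits did not hold the same cells. Used were 206 of 340 at 2 dpa, 208 of 307 at 3 dpa and 33 of 71 at 4 dpa. Exchanging the arms within libraries makes 16 splits, too few for a share under 0.05: for sp6 the real split gave 504 genes and the highest other 567, from exchanging the uninjured library alone (2 of 16 as many as the real one), and for sp8 the real split gave 149 and the highest other 0 (1 of 16).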
